A study of Mus musculus with 10 samples.

How the data were processed

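The deposited files hold raw read counts per Ensembl transcript, 1 file for each of 10 libraries: soleus and TA from 3 male and 2 female wild-type mice. The unit is a count, a whole number of at least 1 in each deposited file, and transcripts with no read are not listed. Per the labels, total RNA was taken with a kit for fibrous tissue, 10 ng entered a preparation called Tag-Seq, and cDNA libraries were made with a Takara SMART-Seq Stranded protocol and sequenced on an Illumina 500 instrument. The submitters' processing notes name bcl2fastq, Trimmomatic 0.32 and FastQC and the genome build GRCm38.p4. The aligner and the counting tool were not given in the sources used here. No strain, age or batch was given.

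Transcripts were matched to the GENCODE M21 annotation of GRCm38 by identifier, ignoring the version, and summed to genes. Of 40414 listed transcripts 40359 matched, and 55 did not match and were left out, with their counts, of the library sizes. Counts were found for 20009 genes, and 28 symbols were shared by more than 1 gene and were kept apart by gene identifier. Totals per library ran from 726414 to 961844 counts. Intervals and floors cover counting error only, since the files give no molecular identifiers.

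What the files count was tested against the annotated sequences. In 3318 genes with several transcripts and at least 100 counts, 62 of 1516 transcripts with no 31-mer of their own had a read (4.09%), against 7783 of 10871 transcripts with more than 100 such 31-mers (71.6%). The latter held 95.0% of the counts. Genes whose transcripts overlap are therefore counted in part, and a comparison of levels between genes, or of shares among genes, carries that limit. A gene compared between muscles carries it too where the muscles use different transcripts of that gene. In each library 17.2% to 28.4% of counts fell on Gm20594, a transcript of 449 bases that is 88.4% identical over 439 bases to the mitochondrial ribosomal RNA mt-Rnr2, by blastn 2.17.0+. A further 3.85% to 6.26% fell on Cep295. The Gm20594 share was 22.1% to 28.4% in soleus and 17.2% to 20.9% in TA, with no overlap. Outside both genes, soleus libraries had 513984 to 632144 counts and TA libraries 611106 to 696675. Depth on the other genes thus tended to be lower in soleus.

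Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr by the 4 groups of tissue and sex, which left 5115, and scaled by TMM. Levels are counts scaled to library size (CPM). Tissue was tested with the edgeR quasi-likelihood F test with sex as a covariate. Sex within each muscle, and the interaction, were tested in a model with a mean for each of the 4 groups. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Gene lists and marker lists, 33 in number and fixed before the data were examined, were tested with camera at a preset correlation of 0.01 where at least 3 members were tested, which left 28, and again with an estimated correlation. Calls of members were also adjusted over the list alone. Shares of 4 adult myosin heavy chain genes in their sum were compared with an exact 2-sided permutation test over the 252 splits of 5 against 5 libraries, adjusted over 4 genes. Principal components used log2 CPM of the 500 most variable genes with a prior count of 2. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 handled the tables, tests and plots.

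Replicate numbers were read as mice, within each sex. After tissue and sex means were removed, soleus and TA libraries of the same number correlated across genes with r from 0.183 to 0.239 in the 3 male pairs. The 2 female pairs have by construction 1 shared value, 0.285. Removing the means also ties the values of the 3 male pairs to each other. Between male libraries of different numbers the highest r was -0.0705. The correlations therefore cannot show by themselves that 1 number is 1 mouse. By the rule set beforehand, a correlation over 0.1 in every pair, they allowed a fit with the mouse as a block as an alternative.

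Genes named in the text followed a rule written before the data were examined. For tissue they were the 10 largest fold changes in each direction among called genes with a mean of at least 10 CPM and the same direction in all 5 mice, without gene models, clones and pseudogenes. Up to 4 members with the smallest p of each list were added, with members whose failure to pass is the point, and Myh1, Myh2, Myh4 and Myh7. For sex they were the 5 largest in each direction per muscle whose groups did not overlap, with the sex-linked lists. A gene with no count in a group was given a lower bound against a floor of 3 counts over that group, and a gene with 1 to 3 counts a ratio with its 95% exact counting interval.

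Alternatives were DESeq2 size factors, upper-quartile scaling, the DESeq2 Wald test, no filter on low counts, a mean of at least 5 CPM, library sizes without mitochondrially encoded genes, leaving out each library, the mouse as a block, no sex term, a fold threshold of 1.5, fits within 1 muscle, and all listed myosin heavy chain genes as the denominator. Protein-coding transcripts only, library sizes without Gm20594 and Cep295, and leaving out both libraries of female mouse 2 were added after seeing the data. The fit was tested on simulated data of the same sizes with 100 genes changed 2-fold and 100 changed 4-fold, and made 2 or 3 false calls in each comparison. Simulated libraries were drawn independently, with no effect shared by the muscles of a mouse and no outlying library. These rates need not hold for the real data.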

Results

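Soleus, a slow-twitch muscle of the mouse calf, was compared with tibialis anterior (TA), a fast-twitch muscle of the shin, in 10 RNA sequencing libraries from 3 male and 2 female wild-type mice. Fold changes are log2 values of soleus over TA, with the standard error (SE) of the fit, so a negative value is higher in TA. Each tissue had 5 libraries. Adjusted p-values are from edgeR across 5115 tested genes. Counts fall mainly on transcripts with sequence of their own, so levels of different genes are not on a common scale.

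Genes of the slow contractile apparatus were among the largest differences toward soleus. Myh7, the slow myosin heavy chain (chromosome 14, 54970684 to 54994626), had a log2 fold change of 11.97 (SE 0.42, n = 5 per tissue). It had 9717 counts over the soleus libraries and 2 over the TA libraries, a ratio of 5361 with a 95% counting interval of 1484 to 44270. Tnnc1, the troponin C of slow and cardiac muscle, differed by 11.00 (SE 0.45). Tpm3, the slow tropomyosin, differed by 9.23 (SE 0.36). Myl3, a slow essential light chain, differed by 7.77 (SE 0.39), and Atp2a2, the slow-fiber and cardiac calcium pump of the sarcoplasmic reticulum, by 7.40 (SE 0.30). Tnni1, the slow troponin I, had no count in TA and was at least 388-fold higher in soleus, against a floor of 3 counts over the TA group. Myl2, the slow regulatory light chain, was at least 279-fold higher, and Tecrl, a gene of the endoplasmic reticulum best known from heart, at least 117-fold higher, against the same floor. Tnnt1, the slow troponin T, had 1 count in TA, a ratio of 355 with a counting interval of 63.3 to 14080. Myh6, the alpha cardiac myosin, also had 1 count in TA, a ratio of 173 with an interval of 30.6 to 6885. These 10 genes were higher in soleus in 5 of 5 mice, and all remained called in each fit that left out 1 library.

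The largest differences toward TA, by the rule for naming genes, included Myh4, Pvalb, Mybpc2 and Actn3 of the fast sarcomere list. Myh4, the IIb myosin heavy chain (chromosome 11, 67238029 to 67260446), differed by -11.86 (SE 0.45, n = 5 per tissue). It had 1 count over the soleus libraries and 6496 over the TA libraries, a ratio of 5888 with a counting interval of 1056 to 232600. Pvalb, the calcium buffer parvalbumin, differed by -6.64 (SE 0.37). Mybpc2, the fast myosin-binding protein C, differed by -6.24 (SE 1.11), and Actn3, the alpha-actinin of fast fibers, by -5.74 (SE 0.54). Cdh4, a cadherin, had 3 counts in soleus, a ratio of 54.1 with an interval of 18.2 to 264.7. Mss51, a mitochondrial regulator of fast muscle, differed by -5.20 (SE 0.52), and Tmem233, a membrane protein, by -4.87 (SE 0.37). Mettl21e, a methyltransferase of muscle, differed by -4.65 (SE 0.41), Kcnc4, a potassium channel, by -4.52 (SE 0.25), and Mylk4, a myosin kinase, by -4.50 (SE 0.37). These 10 genes were higher in TA in 5 of 5 mice and remained called in each fit that left out 1 library.

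Across all genes, 1126 of 5115 differed between the tissues at an adjusted p under 0.05, with 561 higher in soleus and 565 higher in TA. At an unadjusted p under 0.05 there were 1725 genes, against 256 expected by chance. Of the 1126 genes, 691 differed more than 2-fold, 369 toward soleus and 322 toward TA. DESeq2 called 1015 genes, 923 of them also called by edgeR. A fit with each mouse as a block called 1207 genes, of which 1069 were shared. Fold changes fitted separately in males and females correlated across all 5115 tested genes (Pearson r = 0.734, genes are not independent replicates), and 3478 of them had the same sign. In simulated data of the same sizes, with libraries drawn independently, 36 of 100 genes changed 2-fold and 84 of 100 changed 4-fold were recovered. A 2-fold change was thus often missed there.

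Metabolic genes divided by pathway. In the list of glycolysis and glycogen genes, 15 of 19 tested were higher in TA and 0 higher in soleus (camera adjusted p = 1.01e-21), and 16 were higher in TA adjusted over the list alone. Gpd1, which links glycolysis to glycerol phosphate, differed by -3.85 (SE 0.21), Phkg1, the catalytic subunit of muscle phosphorylase kinase, by -3.27 (SE 0.18), and Gapdh, a glycolytic dehydrogenase, by -1.96 (SE 0.16). Hk2, the insulin-regulated hexokinase, did not pass (-0.03, SE 0.17). Among genes of mitochondrial beta-oxidation, 9 of 15 were higher in soleus and 0 in TA, and 13 were higher in soleus adjusted over the list alone (camera adjusted p = 0.000195, adjusted p = 0.152 with an estimated correlation). Acadm, the medium-chain acyl-CoA dehydrogenase, differed by 0.94 (SE 0.14) and Acaa2, the last enzyme of the cycle, by 1.11 (SE 0.19). In the list of fatty acid uptake and storage, 3 of 11 were higher in soleus and 0 in TA, and 6 were higher in soleus adjusted over the list alone (camera adjusted p = 0.000195, adjusted p = 0.152 with an estimated correlation). These 3 were Lpl, lipoprotein lipase, at 2.16 (SE 0.13), Dgat2, which makes triglyceride, at 3.16 (SE 0.26), and Fabp3, the muscle fatty acid carrier, at 2.67 (SE 0.30). Tested genes of the adipocyte marker list, Car3 among them, moved the same way (3 of 3 higher in soleus, median 2.09). Being on that list does not show that a gene was read from adipocytes, and which cells these reads came from was not tested. Idh2, the mitochondrial isocitrate dehydrogenase that makes NADPH, differed by 3.85 (SE 0.30).

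The sarcomere lists were the other calls that held with an estimated correlation, beside glycolysis and glycogen. All 12 tested slow sarcomere genes were higher in soleus, also adjusted over the list alone (median log2 fold change 7.76, camera adjusted p = 5.15e-91, adjusted p = 0.000215 with an estimated correlation). Of 16 fast sarcomere genes, 14 were higher in TA and 1 in soleus, with the same counts adjusted over the list alone (median -2.12, camera adjusted p = 7.39e-26, adjusted p = 0.00502 with an estimated correlation). The exception was Actn2, the alpha-actinin of all fibers, at 1.46 (SE 0.36), and Tnnt3, the fast troponin T, did not pass (-0.25, SE 0.17). Myoz1, a calcineurin-binding protein of the fast Z-disc, differed by -3.08 (SE 0.23). The excitation-contraction and calcium list had 2 of 20 genes higher in soleus, Atp2a2 and Sln, and 8 higher in TA, or 3 and 9 adjusted over the list alone (camera adjusted p = 0.0242, adjusted p = 0.152 with an estimated correlation). Its adjusted p rose to 0.0523 without soleus male replicate 2, and the call was also lost without TA male replicate 3. Sln, the pump inhibitor sarcolipin, which was named after its values were seen, differed by 5.24 (SE 0.47), Atp2a1, the fast calcium pump, by -2.23 (SE 0.15), and Camk2a, a calcium-dependent kinase, by -2.12 (SE 0.16).

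**Figure D1:**
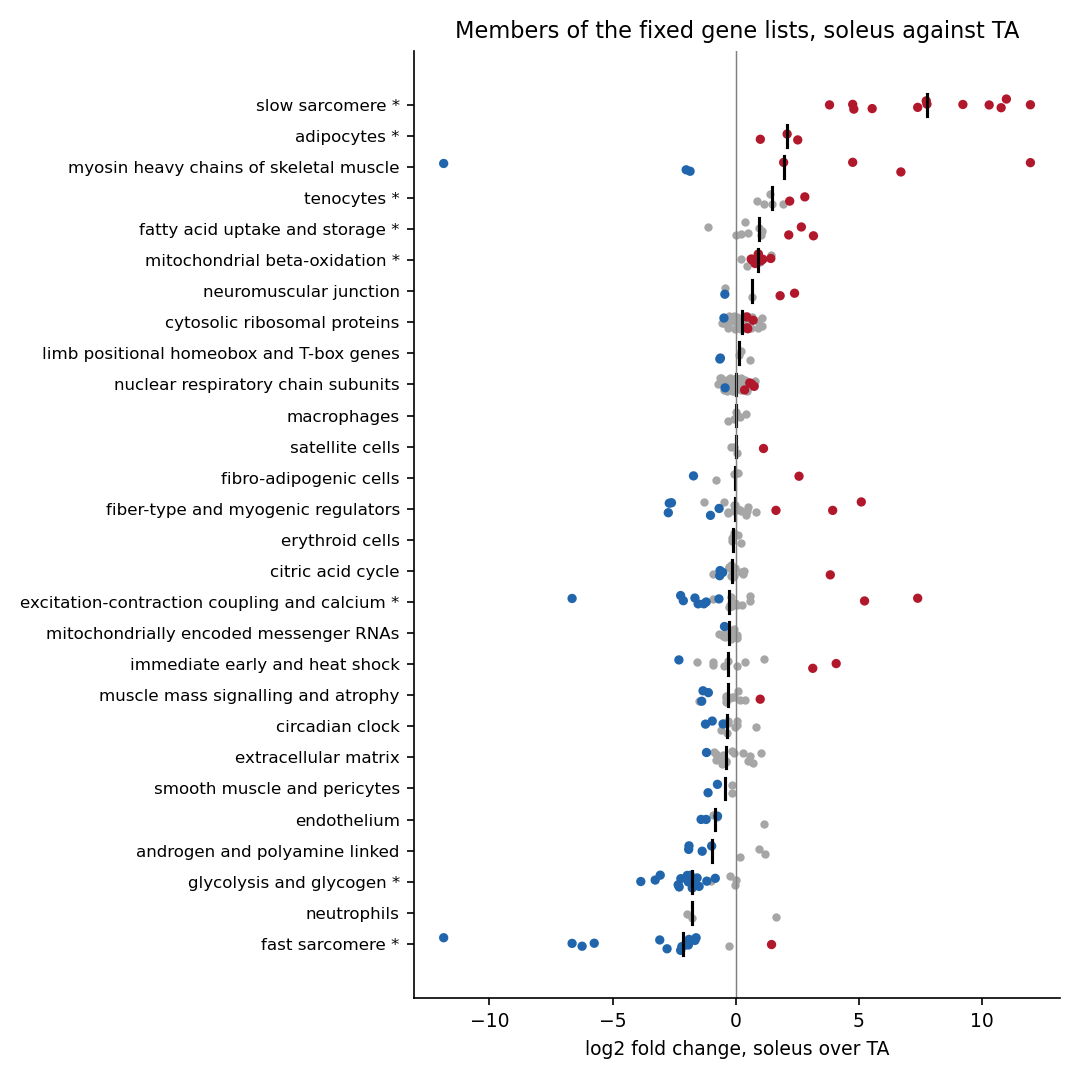
Log2 fold change, soleus over TA, of each tested member of the 28 fixed lists with at least 3 tested genes. Points are genes, red (higher in soleus) or blue (higher in TA) at an adjusted p under 0.05 and grey otherwise, black bars are list medians, and an asterisk marks the 8 lists called with the preset correlation. The slow sarcomere list has a median of 7.76 and the fast sarcomere list a median of -2.12.

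Transcription factors of fiber type differed singly, and their list was not called (3 of 24 higher in soleus, 5 in TA, camera adjusted p = 0.662, or 4 and 5 adjusted over the list alone). Prox1, a homeobox gene of slow fibers, differed by 3.94 (SE 0.40). Maf at -2.73 (SE 0.25) and Mafa at -2.70 (SE 0.22), of the large Maf family, and Sox6, a repressor of slow genes, at -2.61 (SE 0.34) were higher in TA. The median of the list was -0.04 and its mean 0.05. Among androgen and polyamine linked genes, 4 of 7 were higher in TA and 0 in soleus (4 and 1 adjusted over the list alone, camera adjusted p = 0.0761). The list was called in 3 of 10 fits that left out 1 library, with the smallest adjusted p, 0.015, without soleus female replicate 2. It was also called with protein-coding transcripts only (0.0362) and with no filter (0.0132). The genes included Sms, spermine synthase, at -1.91 (SE 0.18). Of 14 genes of muscle mass signalling and atrophy, 1 was higher in soleus and 3 in TA, also adjusted over the list alone (camera adjusted p = 0.367), among them Smad3, a transducer of myostatin signals, at -1.32 (SE 0.25). The circadian list had 3 of 12 genes higher in TA and 0 in soleus, also adjusted over the list alone (camera adjusted p = 0.259), including Bhlhe41, a clock repressor, at -1.22 (SE 0.20). At the neuromuscular junction 2 of 5 genes were higher in soleus and 1 in TA, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.359). Chrna1, an acetylcholine receptor subunit, differed by 2.39 (SE 0.34). In the immediate early and heat shock list 2 of 11 were higher in soleus and 1 in TA, also adjusted over the list alone (camera adjusted p = 0.786, median -0.31 and mean 0.20). Hspa1a, an inducible heat shock protein, differed by 4.08 (SE 0.81), and by 2.46 without soleus female replicate 2, which had 420 CPM against at most 46.7 in the other soleus libraries.

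Genes of oxidative phosphorylation differed little between the muscles. Of 49 nuclear respiratory chain subunits, 4 were higher in soleus and 1 in TA (median 0.03, camera adjusted p = 0.759), or 2 and 0 adjusted over the list alone. Cox8a, a cytochrome oxidase subunit, differed by 0.75 (SE 0.16). Of 12 mitochondrially encoded messenger RNAs, 0 were higher in soleus and 1 in TA by edgeR, also adjusted over the list alone (median -0.26, camera adjusted p = 0.299). In the citric acid cycle list 1 of 18 was higher in soleus and 3 in TA, also adjusted over the list alone (camera adjusted p = 0.786, median -0.15 and mean 0.02). Of 38 cytosolic ribosomal protein genes, 4 were higher in soleus and 1 in TA, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.259). The limb positional list had 0 of 5 higher in soleus and 2 in TA, also adjusted over the list alone (camera adjusted p = 0.759, median 0.12 and mean -0.07).

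Markers of other cell types differed mainly in single genes, and 2 marker lists, adipocytes and tenocytes, were called with the preset correlation only. Endothelial genes Kdr (-1.40, SE 0.25) and Cdh5 (-1.20, SE 0.24), a growth factor receptor and a junction cadherin, were higher in TA. Their list had 3 of 6 genes higher in TA and 0 in soleus, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0761). This list was called without TA female replicate 2 (0.00371), in the fit with each mouse as a block (0.0473), with protein-coding transcripts only (0.0287) and with no filter (0.00568). Notch3, a receptor of mural cells, differed by -1.12 (SE 0.16), and 2 of 4 genes of smooth muscle and pericytes were higher in TA, also adjusted over the list alone (camera adjusted p = 0.151). All 3 tested genes of the adipocyte list were higher in soleus, also adjusted over the list alone (camera adjusted p = 0.0487, adjusted p = 0.244 with an estimated correlation). This call held in 6 of 14 fits, the reported one included. It was lost without soleus female replicate 1 (0.0923), TA female replicate 2 (0.062) or TA male replicate 1 (0.0593), 2 (0.0614) or 3 (0.0501), and with each mouse as a block (0.0601) or DESeq2 size factors (0.0504). The 3 genes of this list were Cidea, a lipid droplet protein, at 2.52 (SE 0.49), Adipoq at 2.09 and Car3 at 1.00. In soleus female 2 Car3 held 4483 of the 4512 CPM on this list. The libraries do not show which cells its counts came from. Tenocyte genes were higher in soleus for 2 of 7, or 6 adjusted over the list alone (camera adjusted p = 0.0487, adjusted p = 0.611 with an estimated correlation), and that call held in 7 of 16 fits, the reported one included. It was lost in 7 of the 10 fits that left out 1 library, with the largest adjusted p, 0.107, without soleus female replicate 1, and with DESeq2 size factors (0.0504). Without soleus female replicate 2 it was 7.84e-06. Comp, a tendon matrix protein, differed by 2.81 (SE 0.56). In the fibro-adipogenic list, Cd34 was higher in soleus (2.58, SE 0.53) and Smoc2 in TA (-1.71, SE 0.37), 1 and 1 of 6, also adjusted over the list alone (camera adjusted p = 0.786, median -0.02 and mean 0.02). Of 4 satellite cell genes, Sdc4, a syndecan, was higher in soleus (1.12, SE 0.20), the same 1 adjusted over the list alone (camera adjusted p = 0.688). In the extracellular matrix list, 1 of 16 differed, Col4a2 of the basement membrane at -1.21 (SE 0.30), the same 1 adjusted over the list alone (camera adjusted p = 0.662). edgeR called 0 of 6 macrophage genes (camera adjusted p = 0.935, mean 0.05 and camera direction down), 0 of 6 erythroid genes (0.786) and 0 of 3 neutrophil genes (0.935), with 0 adjusted over the list alone. Lists with fewer than 3 tested genes had no list test. Dsp, the 1 tested skin gene, had no count in TA and was at least 18.0-fold higher in soleus against the floor of 3 counts over the group. The 1 tested Schwann cell gene, Mbp, did not pass (-0.37, SE 0.48), and no lymphocyte gene was tested. Of the Y-linked genes 1 of 2 was higher in soleus, also adjusted over the list alone, Kdm5d, a demethylase gene, at 1.95 (SE 0.55), a call lost without TA female replicate 2 (adjusted p = 0.0762) or 1 (0.0722), and the value was 1.12 without soleus female replicate 2. The Kdm5d value includes reads in female soleus libraries, which cannot be expression from a Y chromosome, as described with the sex-linked genes. Of the X-linked genes edgeR called 0 of 2, also adjusted over the list alone.

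Of the counts on 4 adult myosin heavy chain genes, Myh7 made up nearly all in soleus and Myh4 nearly all in TA. As shares of the counts on Myh1, Myh2, Myh4 and Myh7, Myh7 was 98.8% ± 0.416 in soleus and 0.0306% ± 0.0684 in TA (SD, n = 5 each, exact 2-sided permutation adjusted p = 0.0106). Myh4 was 0.0111% ± 0.0249 in soleus and 96.3% ± 1.83 in TA (SD, n = 5 each, exact permutation adjusted p = 0.0106). Myh1, the IIx form, was 0.442% ± 0.305 in soleus and 3.29% ± 1.57 in TA (SD, n = 5 each, exact permutation adjusted p = 0.0106). Myh2, the IIa form, was 0.762% ± 0.371 in soleus and 0.355% ± 0.324 in TA, which did not pass (SD, n = 5 each, exact permutation adjusted p = 0.0952). These shares rest on 859 to 2411 counts per library, and since only reads particular to a transcript seem to be counted, they are not shares of fiber types. They depend on the genes summed: Myh8, the perinatal form, is outside this sum and had a mean of 819 CPM in TA. With all listed myosin heavy chains as denominator, the difference of soleus minus TA went from -96.3 to -61.3 percentage points for Myh4, from -2.85 to -1.60 for Myh1 and from 98.8 to 82.4 for Myh7, and that of Myh2 passed (0.432, exact permutation adjusted p = 0.0397). With the pairs of muscles from 1 mouse permuted as a block, the smallest p that 5 pairs allow is 0.0625. By the gene test Myh1 differed by -2.01 (SE 0.47) and Myh2 by 1.95 (SE 0.54), the latter lost without TA female replicate 2 (adjusted p = 0.0586), soleus male replicate 1 (0.053) or soleus male replicate 2. Of the 7 tested myosin heavy chain genes, 4 were higher in soleus and 3 in TA, also adjusted over the list alone (camera adjusted p = 0.0582), with Myh7b, a relative of Myh7, at 4.76 (SE 0.47). The list was called in 3 of 10 fits that left out 1 library, with the smallest adjusted p, 0.0202, without soleus male replicate 1.

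**Figure D2:**
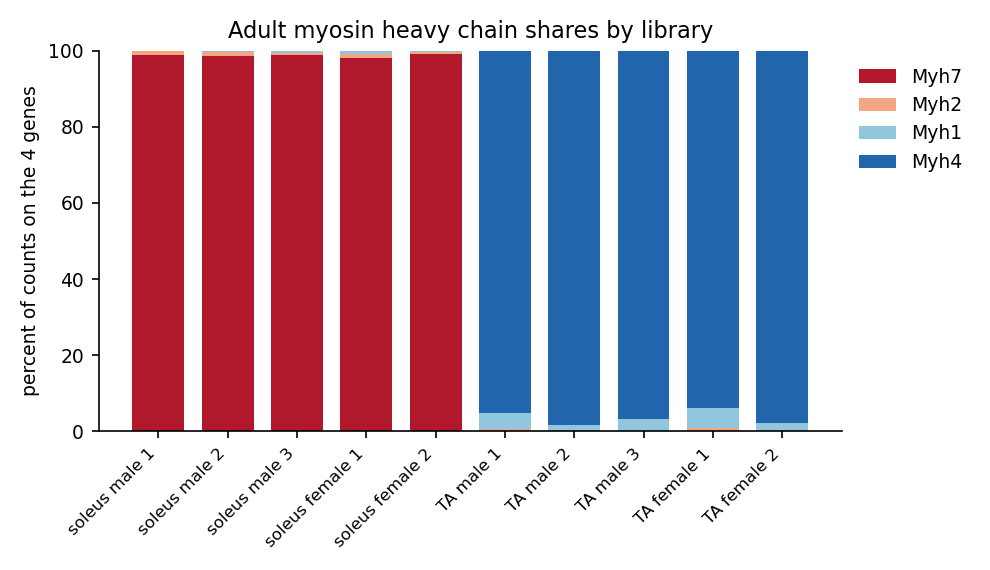
Share of each of 4 adult myosin heavy chain genes in their summed counts (percent, vertical axis) in each of the 10 libraries. Bars are single libraries, with Myh7 between 98.2% and 99.3% in soleus and Myh4 between 93.8% and 98.3% in TA.

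Tissue also separated the libraries on the first principal component. It carried 55.7% of the variance of the 500 most variable genes, with soleus libraries between -32.87 and -20.05 and TA libraries between 18.99 and 28.81. The second component carried 23.6%. Male libraries lay between -15.79 and -5.64 on it and female libraries between 1.49 and 32.24. Soleus and TA of female mouse 2 lay at 32.24 and 24.58, and those of female mouse 1 at 1.49 and 10.36.

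**Figure D3:**
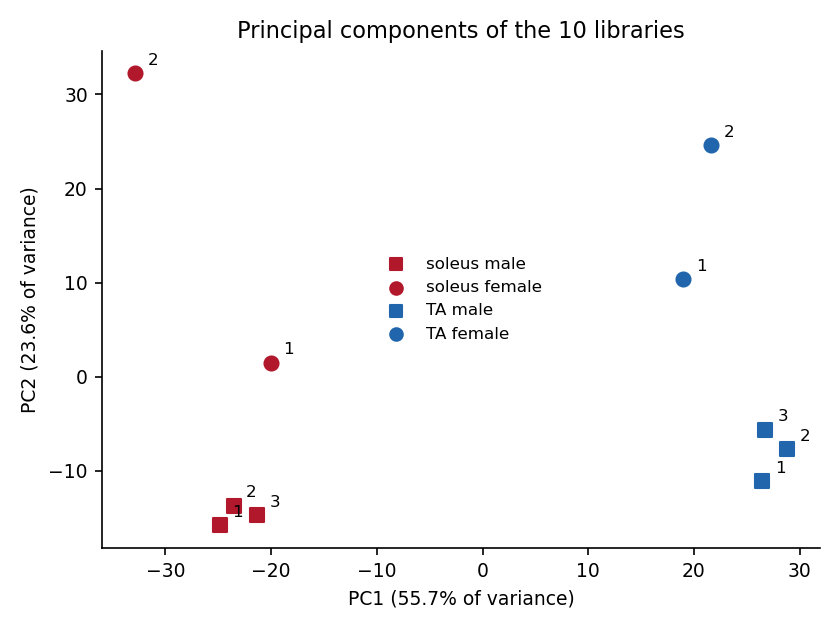
Principal components 1 and 2 of the 10 libraries (scores, arbitrary units), from log2 CPM of the 500 most variable genes. Points are libraries with their replicate numbers, red for soleus and blue for TA, squares for males and circles for females. Tissues separate on the horizontal axis. On the vertical axis males and females do not overlap, and the libraries of female mouse 2 lie farthest from the males.

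Between sexes, the gene with the smallest p in both muscles was Mpp7, a membrane scaffold gene (chromosome 18, 7347959 to 7626866). Its log2 fold change of male over female was -6.44 (SE 0.57) in soleus and -6.39 (SE 0.55) in TA, with 3 male and 2 female libraries each. It remained called in every fit that left out 1 library. AK157302 (chromosome 13, 21495223 to 21497146), a gene annotated near the histone cluster, had no count in female libraries and was at least 14.7-fold higher in male soleus and at least 19.1-fold higher in male TA, against a floor of 3 counts over the female group. Of 10 fits that left out 1 library, its call was lost in 5 in soleus, with the largest adjusted p, 0.095, without soleus female replicate 2. In TA it was lost in 4, with the largest, 0.107, without TA female replicate 2. Nt5dc3, a nucleotidase-like gene, was higher in male TA by 2.32 (SE 0.30) and in male soleus by 1.77 (SE 0.32), and its TA call was lost without TA male replicate 2 (adjusted p = 0.0613). Its soleus call was lost in 6 of 10 such fits, with the largest, 0.118, without soleus male replicate 3. H2-D1, a class I histocompatibility gene, was higher in males by 2.39 (SE 0.34) in soleus and 2.10 (SE 0.34) in TA. Its calls were lost in 2 of 10 such fits in soleus, with the largest adjusted p, 0.0915, without soleus male replicate 2, and in 4 in TA, with the largest, 0.215, without TA female replicate 2. Btg2, an early response gene, was higher in females (-2.55, SE 0.44 in soleus and -3.24, SE 0.45 in TA), and its TA call was lost in 4 of 10 fits that left out 1 library, with the largest adjusted p, 0.0655, without TA male replicate 1. Its soleus call was lost in 5, with the largest, 0.140, without soleus male replicate 1, and the soleus value was -1.68 without soleus female replicate 2.

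In soleus 28 genes differed by sex, 10 higher in males and 18 in females, with 845 at an unadjusted p under 0.05 and 102 called by DESeq2. In TA 33 differed, 14 higher in males and 19 in females, with 596 at an unadjusted p under 0.05 and 69 called by DESeq2. Fits within 1 muscle, which do not pool the spread, called 1 gene in soleus and 84 in TA. The genes called in both muscles numbered 9, and all 9 had the same direction. Both comparisons use the same 5 mice, so this overlap is not a repeat in other animals. They included Mpp7, AK157302, Nt5dc3, H2-D1, Btg2, Carnmt1, Glns-ps1 and Gm10717. Of these, H2-D1, Carnmt1, Glns-ps1 and Gm10717 were named after their values were seen. Of 10 fits that left out 1 library, Carnmt1 was lost in 7 in each muscle, Glns-ps1 in 3 in soleus and 4 in TA, and Gm10717 in 4 in soleus and 7 in TA. The largest adjusted p in soleus were 0.157 (Carnmt1, without soleus female replicate 2), 0.0844 (Glns-ps1, without soleus male replicate 2) and 0.110 (Gm10717, without soleus male replicate 2). In TA they were 0.282 (Carnmt1, without TA female replicate 2), 0.0901 (Glns-ps1, without TA male replicate 2) and 0.298 (Gm10717, without TA female replicate 2). The counts rest on single libraries. A fit without 1 female library leaves 1 female library of that muscle, which has no spread of its own. It also changes the genes tested, with 6194 in place of 5115 without soleus female replicate 1. The soleus count was 1 without soleus male replicate 1, 2 without soleus male replicate 2, 4 without soleus male replicate 3, 10 without TA male replicate 1, 17 without TA male replicate 2, 16 without soleus female replicate 2 and 1022 without soleus female replicate 1. The TA count was 4 without TA male replicate 1, 1 without TA male replicate 2, 4 without TA male replicate 3, 11 without soleus male replicate 2, 15 without soleus male replicate 3, 8 without TA female replicate 2, 162 without soleus female replicate 1 and 159 without soleus female replicate 2. A simulated 4-fold change was recovered for 69 of 100 genes in soleus and 64 of 100 in TA, and a 2-fold change for 10 of 100 in each.

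Further genes with large sex differences were called in 1 muscle. In soleus, Garnl3, a regulator of small GTPases (-3.86, SE 0.53), Gadd45g, a stress response gene (-3.65, SE 0.53), Ifi211 (-3.56, SE 0.58) and Ifi44 (-3.10, SE 0.51), both interferon-inducible, were higher in females. Of 10 fits that left out 1 library, the calls of Garnl3 and Gadd45g were lost in 3, with the largest adjusted p, 0.0915 and 0.110, without soleus male replicate 2. Without soleus female replicate 2 Gadd45g was at -2.10. Those of Ifi211 and Ifi44 were lost in 5, with the largest, 0.117 and 0.190, without soleus female replicate 2. Pcp4l1 was higher in male soleus (2.64, SE 0.48), a call lost in 6 of 10 such fits, with the largest adjusted p, 0.140, without soleus male replicate 1. Its value was 3.97 without soleus female replicate 1. In TA, Apold1, an early response gene of vessels (-2.94, SE 0.38), Myog, the myogenic factor myogenin (-3.32, SE 0.59), and Thbs1, a matrix glycoprotein (-3.12, SE 0.57), were higher in females. Their calls were lost in 3, 6 and 7 of 10 such fits, with adjusted p of 0.0613 without TA male replicate 2, and of 0.239 and 0.282 without TA female replicate 2, in that order. H2-Q6, a class I gene, was higher in male TA (2.62, SE 0.47), a call lost in 6 of 10 such fits, with the largest adjusted p, 0.298, without TA female replicate 2. Of the histone genes Hist1h4a in soleus and Hist1h3d in TA, the female libraries had 3 counts and 1 count, with male ratios of 9.70 (counting interval 3.10 to 48.9) and 30.5 (5.19 to 1232). The call of Hist1h4a was lost in 7 of 10 such fits, with the largest adjusted p, 0.148, without soleus female replicate 2. That of Hist1h3d was lost in 6 of 8, with the largest, 0.201, without TA female replicate 2. Dusp23, a phosphatase gene, was higher in male soleus (2.80, SE 0.53), a call lost in 9 of 10 such fits, with the largest adjusted p, 0.201, without soleus female replicate 2.

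Sex-linked genes were counted thinly. Ddx3y, on the Y chromosome, had no count in female libraries and was at least 7.22-fold higher in male soleus and at least 10.2-fold higher in male TA against the floor of 3 counts over the group, with adjusted p of 0.0599 and 0.0504. It was called without soleus female replicate 1 in both muscles (0.0212 and 0.00924), and in TA also without soleus female replicate 2 (0.0102). The X-linked escape genes Eif2s3x (-0.50, SE 0.20 in soleus and -0.35, SE 0.20 in TA) and Ddx3x (-1.23, SE 0.34 and -0.95, SE 0.34) did not pass over all genes. Adjusted over the list alone, 2 of 2 were higher in females in soleus and 1 of 2 in TA. Ddx3x in soleus was -1.66 without soleus female replicate 1 (adjusted p = 0.000797) and -0.40 without soleus female replicate 2. In TA it was -0.57 without TA female replicate 2, and it was called without soleus female replicate 1 (0.0365) or 2 (0.042). Kdm5d, also on the Y chromosome, did not pass over all genes (-1.40, SE 0.59 in soleus and 0.71, SE 0.83 in TA). Its soleus value, toward females, was -2.10 without soleus female replicate 1 and 0.64 without soleus female replicate 2. Females carry no Y chromosome, so a value toward them cannot be read as expression of this gene. The source of these reads was not tested. Adjusted over the list alone, 1 of the 2 Y-linked genes was higher in males and 1 in females in soleus, and 1 was higher in males in TA.

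The immediate early and heat shock genes were higher in females as a list, with a median of -3.39 in soleus and -3.44 in TA over 11 tested genes. edgeR called 1 of the 11 in each muscle, and 11 and 8 were higher in females adjusted over the list alone. The camera adjusted p was 2.69e-08 in soleus, with adjusted p = 0.581 with an estimated correlation, and without soleus female replicate 2, 1 of the 2 female soleus libraries, it was 0.401. In TA it was 1.23e-15, with adjusted p = 0.262 with an estimated correlation. Erythroid genes were higher in males, with medians of 3.95 in soleus (camera adjusted p = 1.47e-11, adjusted p = 0.581 with an estimated correlation) and 2.46 in TA (camera adjusted p = 3.71e-06, adjusted p = 0.370 with an estimated correlation). Of the 6 tested, edgeR called 0 in either muscle, and 6 and 4 were higher in males adjusted over the list alone. The mitochondrially encoded messenger RNAs were higher in male TA, with a median of 0.80 (camera adjusted p = 6.73e-12, adjusted p = 0.262 with an estimated correlation), 1 of 12 called and 12 adjusted over the list alone. With the preset correlation the citric acid cycle list was called toward males in both muscles (camera adjusted p = 0.0276 in soleus and 8.75e-05 in TA). With an estimated correlation its camera adjusted p was 0.581 and 0.370. The soleus call held in 8 of 10 fits that left out 1 library, and soleus female replicate 2 was among those whose removal lost it. The extracellular matrix list (0.0119) and the tenocyte list (0.0276) were called toward males and the ribosomal protein list (0.0327) toward females in soleus, each at an adjusted p = 0.581 with an estimated correlation. All 3 calls were lost without soleus female replicate 2 (0.952, 0.979 and 0.979), which had 257 CPM over the tenocyte genes against at most 1147 in the other soleus libraries. The erythroid call held without it, at 5.45e-21. The ribosomal protein call held in 4 of 10 fits that left out 1 library. The respiratory chain list (0.000228) was called toward males, and the tenocyte (0.0021) and neutrophil (0.0103) lists toward females, in TA, each at an adjusted p = 0.370 with an estimated correlation. The tenocyte call was lost without TA female replicate 1 (0.197) and the neutrophil call without TA female replicate 2 (0.507). With an estimated correlation no list was called by sex.

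**Figure D4:**
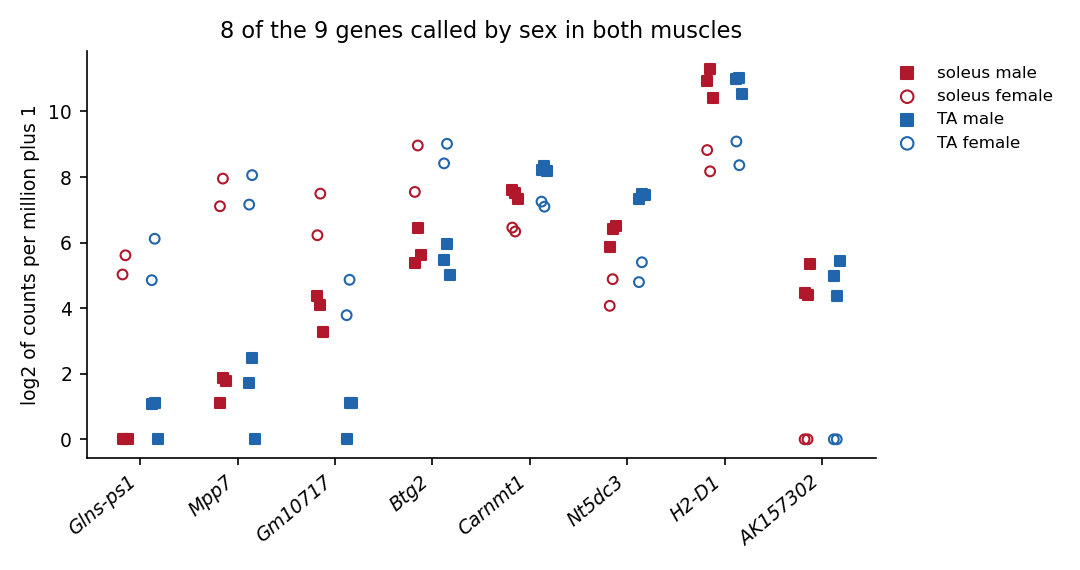
Log2 of CPM plus 1 (vertical axis) of 8 of the 9 genes called between males and females in both muscles. Points are single libraries, red for soleus and blue for TA, filled squares for males and open circles for females. Mpp7 lies higher in the female libraries of both muscles, and AK157302 has no count in them.

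A sex difference that itself differed between the muscles was called for 0 genes by edgeR, with 351 at an unadjusted p under 0.05 and 2 called by DESeq2. The smallest adjusted p was 0.208. The 2 counts that follow come from fits with 1 female soleus library, which has no spread of its own. Without soleus female replicate 1 the count was 79, and without soleus female replicate 2 it was 4. The mitochondrially encoded messenger RNAs (median -0.75, camera adjusted p = 1.56e-06) and the tenocyte genes (median 2.38, camera adjusted p = 2.20e-07) were called as lists, each with adjusted p = 0.322 with an estimated correlation. The fast sarcomere list (median -0.45, camera adjusted p = 0.00409, adjusted p = 0.322 with an estimated correlation) and the erythroid list (median 1.76, camera adjusted p = 0.00467, adjusted p = 0.592 with an estimated correlation) were also called. Without soleus female replicate 1 the mitochondrially encoded (0.110), fast sarcomere (0.530) and erythroid (0.544) calls were lost. The erythroid call held in 7 of 10 fits that left out 1 library. A positive median here is a male over female difference that was larger in soleus.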

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

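The tests of genomic position and both tests of the immediate early genes were chosen only after the result was seen, as were the conditions on a single female library and on reads shared between genes, the neutrophil ratio without Cxcr2 and the count with like-named neighbours as 1, described with their tests.

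The difference between soleus and TA exceeded what other splits of the libraries gave. Of 100 splits into 5 and 5 libraries, drawn from the 126 possible, 1 called as many as 1126 genes, the real one, and the highest of the others was 18. By the bound set beforehand this argues against chance alone, if the libraries are taken as unpaired. The other splits mix soleus and TA within a group, which adds to their spread and can lower their counts. The 15 other drawn splits that also part all 5 mice called at most 0 genes by edgeR, against 1126, and the others part fewer mice. Only such splits match the pairing of muscles, and they are too few to give a p under 0.05.

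Soleus female 2 stood apart from the other 4 soleus libraries, with 22862 listed transcripts, 15070 genes with a read and 3.54% of the counts outside Gm20594 and Cep295 on retained introns. The counted Cep295 transcript is itself annotated as a retained intron, and over all counts the share was 8.21%, against at most 7.25% in the other soleus libraries. Thinned to 513984 counts, it still listed 21003 transcripts, against 13314 to 15669 in the other 9 libraries, so greater depth is argued against. Unspliced RNA or genomic DNA remains open: 435 olfactory and vomeronasal receptor genes had a read after thinning, against at most 239 elsewhere, between the bounds set beforehand. For cells of a marker type, 1 of 12 marker lists passed the bound set beforehand. The neutrophil list reached 6.72 times the highest other soleus library, with 5 of its 6 genes highest here, and 6.57 times without Cxcr2. The list rests on 93 counts, 51 of them on Cxcr2 and 0 on Ly6g, and on a comparison with soleus libraries alone. Such cells are a candidate only, since passing the bound does not tie them to the added transcripts. The neutrophil call toward females in TA was lost without TA female 2. That library, thinned, listed 14702 transcripts, within the range given above. Whether such cells account for the added transcripts was not tested. No label sets this library apart from the other soleus libraries in a group of its own, so no biological difference between groups was tested for it.

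The 52 genes called between male and female mice in either muscle were on autosomes for 51 and on neither sex chromosome. Of these 51, 22 had another called gene within 5 Mb, against a mean of 11.9 in 10000 random draws (permutation p = 0.0094), which a difference of genomic segments between the males and females could give. Neighbours whose symbols share their opening letters were then counted as 1, a stand-in for families that can also join unrelated genes. Counted so, in the draws too, 17 had another, against 11.8 (permutation p = 0.119), so this remains open. Reads shared with near-identical genes also remain open: 38.5% of the called genes, 20 of 52, had over 10% of their 31-mers in another gene, against 13.9% of the other tested genes (exact Fisher p = 1.18e-05), past the bound set beforehand. A condition added afterwards, that such reads are counted, was not met, since 17 of 3023 genes with no 31-mer of their own had a read, against 19469 of 45686 genes with more than 100. A sex difference itself was not told apart from either, since the labels give no strain or litter.

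The immediate early and heat shock genes, called toward females with the preset correlation, were not raised in all female libraries. Their median log2 ratio over the male mean of the same muscle was 0.463 in soleus female 1, against 2.56 in TA female 1, 3.81 in soleus female 2 and 3.15 in TA female 2. Under the bound set for this test that would exclude a sex difference shared by both muscles of each mouse, but 1 library that lacks the rise excludes nothing, a condition added after the value was seen, so this remains open. Btg2 was raised in soleus female 1 too, at 186 CPM against 40.9 to 87.0 in the male soleus libraries. In female mouse 1 the median log2 ratio of TA over soleus was 2.51, against 0 to 0.424 in the other 4 mice. This follows from the values that prompted the test, so it decides nothing on handling of single muscles, which also remains open. The labels give no times or order of dissection, so a difference by sex limited to some muscles stays open and was not tested.

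A library far from the other 4 of its tissue was found in 34 of 272 groups of library measures, myosin shares and named genes. Chance gives about 1 in 20 groups, but the groups are not independent, Myh4 and Myh7 enter both as gene and as share, and in 6 of the 34 the other 4 libraries had no count, so that any count stood apart. The number is therefore not set against chance. Soleus female 2 accounted for 15. In log2 CPM plus 1, it was lowest for Fabp3 (9.36), Acaa2 (8.43), Etfa (7.38), Acadl (9.36), Dlat (7.44), mt-Atp6 (6.68), Acta2 (4.58), Dpp4 (1.72), Chad (1.72), Fmod (5.996) and Tnmd (1.72), and highest for Hspa1b (8.09). TA female 2 was highest for Hoxc10 (8.12) and lowest for Kdr (5.65), Cidea (0) and Mrc1 (5.99). TA male 3 was highest for Mss51 (6.36) and Myh7 (1.73, a share of 0.153%), and soleus male 1 was highest for Myh4 (1.12, a share of 0.0557%) and lowest for Myh1 (0). TA male 2 was highest for Tnnt1 (1.11) and Phkg1 (8.56) and lowest for Acta2 (4.79). Soleus male 3 was lowest for Phkg1 (4.45), mt-Nd3 (4.28) and Vwf (2.57). TA female 1 was highest for Myh6 (1.11) and lowest for Camk2a (6.76), and TA male 1 was highest for Ndufb3 (7.49).

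Transcripts absent from the annotation, 55 in number, held 2597 counts over the 10 libraries, above the limit of 3 that a count of 0 allows. They entered no comparison.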

How the results depend on the processing

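The alternatives of protein-coding transcripts only, library sizes without Gm20594 and Cep295, and leaving out both libraries of female mouse 2 were chosen after seeing the data. The count of genes differing between soleus and TA stayed within 1.5 times 1126 under every setting but a fold threshold of 1.5, which by its construction gave 468. Leaving out 1 library gave 892 (soleus male replicate 2) to 1353 (soleus female replicate 1), and the fit with each mouse as a block gave 1207. For other results the cause of a change was not tested. Fits without 1 female library leave 1 female library of that muscle, which limits their sex and interaction counts. The soleus sex count of 28 became 102 with the DESeq2 Wald test, 449 with no filter and 1 in a fit of soleus libraries only, and ran from 1 (without soleus male replicate 1) to 1022 (without soleus female replicate 1). The TA sex count of 33 became 69 with DESeq2, 240 with no filter, 84 in a fit of TA libraries only and 58 without both libraries of female mouse 2, and ran from 1 (without TA male replicate 2) to 162 (without soleus female replicate 1). The interaction count of 0 became 2 with DESeq2, 58 with no filter and 10 without both libraries of female mouse 2. It ran from 0 to 79 (without soleus female replicate 1), and it was 0 with the block. The 8 called lists became 3 with an estimated correlation and 15 with no filter, and ran from 5 (without soleus male replicate 2) to 10 (without TA female replicate 1). With the block there were 8, of which 7 were shared: the adipocyte list was lost (0.0601) and the endothelial list gained (0.0473). The myosin differences of -2.85 percentage points for Myh1, -96.3 for Myh4 and 98.8 for Myh7 had an exact p = 0.0625 with pairs permuted as a block, the smallest that 5 pairs can give, which says nothing on stability. With all listed myosin heavy chains as denominator these differences were -1.60, -61.3 and 82.4 percentage points, and that of Myh2 passed, at 0.432. Of 125 genes named for tissue, 68 kept direction and side of the threshold in all settings that keep every library or leave out mouse 2, and 74 in all that leave out 1 library. Direction changed for 15 of them and for 1 named for sex, none called either way. Ranges over the leave-one-out fits were -0.35 to 0.14 for Acta2, -0.60 to 0.29 for Alas2, -0.35 to 0.20 for C1qa, -0.0450 to 0.55 for C1qc, -0.11 to 0.28 for Cdh15, -0.27 to 0.0888 for Ddx3x, -0.84 to 0.0193 for Ddx3y, -0.0393 to 0.47 for Dpp4, -0.28 to 0.58 for Hba-a1, -0.64 to 0.23 for Hbb-bs, -0.46 to 0.00772 for Heyl, -2.56 to 0.69 for Retnlg, -0.84 to 0.54 for Slc4a1, -0.35 to 0.0936 for Tagln and -0.54 to 0.19 for Vcam1 in tissue, and -2.10 to 0.64 for Kdm5d by sex in soleus. Without both libraries of female mouse 2 the changed values were 0.0360 for Tagln, 0.14 for Acta2, 0.0763 for C1qa, 0.0250 for Slc4a1 and 0.64 for Kdm5d by sex in soleus. With no sex term they were 0.0307 for Ddx3x, 0.0893 for Alas2, 0.11 for Slc4a1 and 0.0374 for Vcam1. With protein-coding transcripts only they were 0.0207 for Ddx3x and 0.0571 for Vcam1, with DESeq2 size factors 0.00252 for Ddx3x, and with the block 0.00717 for Slc4a1. No scaling moved the median of all genes by more than 0.0778 (log2). The pseudocount alternative does not apply to counts and was not run. In each sex comparison 10 of 100 simulated 2-fold changes were recovered.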

Other observations

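Testing transcripts in place of genes was chosen only after the gene results were seen. Some genes of the sarcomere used different transcripts in the muscles while their summed counts did not differ by the gene test. Of 5089 transcripts tested, 1233 differed between soleus and TA at an adjusted p under 0.05, 639 higher in soleus and 594 in TA. Of 227 genes with several tested transcripts, 17 had transcripts whose fold changes differed from each other (diffSpliceDGE in edgeR, Simes adjusted p under 0.05), and 8 had transcripts called in opposite directions: Dtna, Fgd4, Myh8, Ndufv3, Neb, Rrm1, Tnnt3 and Ttn. In Neb, the giant protein nebulin that sets thin filament length, a protein-coding transcript differed by -6.27 (SE 0.33) and a processed transcript by 3.36 (SE 0.32), each in 5 of 5 mice. The gene as a whole did not pass (-0.11). In Tnnt3, the fast troponin T, a protein-coding transcript had 1 count in soleus and 288 in TA, and another differed by 2.62 (SE 0.41), with the gene at -0.25. In Ttn, the elastic protein titin, a protein-coding transcript had 1 count in soleus and 239 in TA, and another had 39 in soleus and 3 in TA, with the gene at -0.37. In Ndufv3, a subunit of respiratory complex I, protein-coding transcripts differed by -0.86 (SE 0.24) and 2.44 (SE 0.31). Dtna, a dystrophin-associated protein, had protein-coding transcripts at -1.96 (SE 0.31) and 1.85 (SE 0.39). Unlike Neb, Tnnt3 and Ttn, Dtna (-0.71) and Myh8 (-1.85) were also called as genes by edgeR, both higher in TA. Since reads shared by transcripts seem not to be counted, these values cover the parts of each transcript that no other shares, and no explanation of them was tested.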
